A study of Mus musculus with 24 samples.

How the data were processed

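Gene expression was measured by RNA-seq of total RNA (RNeasy Micro kit, per the labels) in 16 mouse samples that form 4 groups of 4. In vitro, satellite cell-derived primary myoblasts from resting muscle of C57BL/6 mice aged 2 to 4 months and carrying Chd4fl/fl alleles were kept proliferating and given adenovirus coding for Cre (AdCRE) or GFP (AdGFP), and were taken 72 hours later. In vivo, satellite cells were sorted 3 days after cardiotoxin injury from Chd4dPax7ER mice and from Chd4fl/fl mice, as SCA1-negative, CD45-negative, alpha7-integrin-positive and CD34-positive cells. In vitro only the case virus coded for Cre, so effects of Cre or of the virus cannot be told apart from those of Chd4 loss. In vivo the case genotype label alone names Pax7ER. Whether Chd4fl/fl mice carried Cre or had the same treatment is not given in the sources used here. The series also holds 8 ATAC-seq samples, which were not analysed here. The labels number the replicates 1 to 4 in each group and do not say that they came from separate animals or cultures, so the p-values measure only the spread between these samples.

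The authors deposited 1 table of RPKM values for each setting, with 46078 genes under Ensembl identifiers and symbols. 551 of these genes have no symbol, and 18546 genes in vitro and 23311 in vivo are listed at 0 in every library. The in vivo values are rounded to 2 decimals. The processing tools that the authors named for their samples are FastQC 0.11.8, cutadapt 1.18, HISAT2 2.1.0, Picard 2.18.15, MACS2 2.1.2, HOMER and DESeq2 3.6, with builds mm10 and GRCm38. Which of them made the RPKM tables, the counting program and the gene lengths are not given in the sources used here. RPKM divides by the reads of a library and by gene length, so genes that share reads with close copies (granzymes, Akr1c and Gst genes, myosin heavy chains) are less certain than others.

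Reads per library cannot be read from RPKM, but in vitro low values move in steps of 1 read and give relative depth. There the deepest library (AdGFP replicate 4) had about 1.64 times the reads of the shallowest (AdGFP replicate 2), and the others lay from 1.08 to 1.29 times. In vivo the values are rounded, and the commonest ratio of low values between libraries was used instead. It gave 1 to 1.13 times, but these values are already divided by the reads of a library, so relative depth in vivo stays unknown. Values summed to between 288659 and 326812 RPKM per library in vitro and between 286802 and 306114 in vivo. Mitochondrial transcripts held 2.90 to 6.56% of these sums in vitro and 9.17 to 12.5% in vivo.

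The case group was compared with its control within each table: AdCRE with AdGFP, and Chd4dPax7ER with Chd4fl/fl. A gene was tested if its RPKM was at least 0.5 in at least 4 of the 8 libraries (13567 genes in vitro, 13344 in vivo). Values were taken as log2(RPKM + 0.5) and fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with moderated variances that follow the mean level. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene passed at an adjusted p under 0.05. Fold changes are on that log2(RPKM + 0.5) scale, which understates changes of low genes, and SE is limma's moderated standard error. Levels are mean RPKM ± SD of 4 libraries. Chd4 itself was also tested with an exact permutation test, repeated within the pairs in vitro. Fold changes of the 2 settings were compared for 11941 genes tested in both, with a t test on their difference and combined standard errors; levels were not compared across the tables.

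In each setting, deviations of libraries from their group mean were correlated between same-numbered libraries. These correlations were 0.711 to 0.856 in vitro, so the replicate number pairs those samples, and -0.0967 to 0.0499 in vivo, where it does not. A fit with the replicate number as a block is therefore given beside the in vitro results where it changes a call or moves a count by more than 1.5 times.

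Before the data were examined, 29 gene lists were fixed from general knowledge: NuRD complex, satellite cell identity, Notch and quiescence, myogenic differentiation, cardiac, smooth muscle, neuronal, adipogenic, chondrogenic and osteogenic, epithelial, germline, imprinted, cell cycle, p53 targets, senescence-associated secretion, interferon response, extracellular matrix, TGF-beta and BMP targets, immediate early and heat shock, glycolysis, and markers of macrophages and leukocytes, neutrophils, endothelium, fibroblasts and fibro-adipogenic progenitors (FAP), pericytes, Schwann cells and glia, mature myofibres, erythroid cells and tenocytes. A list with at least 3 tested members was tested with limma's camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals; fry, a rotation test that treats the list on its own, was a further test. List p-values were adjusted over the lists of a comparison. Counts of list members below are of tested members, and the expression filter left out most members of some lists. Only 6 of 22 neuronal and 5 of 24 cardiac genes were tested in vivo, and 8 of 19 interferon response genes in vitro. Some members were above the filter in the case group alone, which tilts such counts towards higher. Also fixed then were the 10 genes named per direction by size of change among those that passed with groups that do not overlap, the up to 4 genes named per list, the comparisons, and most alternatives: other pseudocounts (0.1 and 1), no filter or RPKM of at least 1, TPM, median-ratio and quantile scaling, limma without the trend or with array weights, the replicate block, a threshold of 0.01, a minimum of 2-fold, and each library left out. Some genes that the naming rule gives are not reported here. A sex term, the block for the cultures alone in the cross-comparison, the alternatives of the blocked fit, and the permutation within pairs were added later.

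Recovery was tested on simulated data, with 100 genes changed at each size. Apart from the differences that same-numbered cultures share, noise was drawn for each gene on its own, from a normal distribution with that gene's SD. Genes of the data vary together, so the shares below come from a simpler setting. The fit recovered 67% of changes of 1 on the log2 scale in vitro and 61% in vivo, and 96% and 92% of changes of 2. With the block the shares were 91% and 97% in vitro, where 13 of 201 calls were unchanged genes. Without the block these were 0 of 163 calls in vitro and 9 of 162 in vivo. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.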

Results

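Chd4 encodes an ATPase of the NuRD chromatin remodelling complex, and its own transcript (ENSMUSG00000063870) was examined first in every sample. In the cultures, AdCRE replicates 1 to 4 held 15.8, 23.9, 21.3 and 22.1 RPKM and AdGFP replicates 76.2, 67.8, 70.8 and 85.5. Chd4 thus fell to 27.7% of control (20.8 ± 3.49 against 75.1 ± 7.75, n = 4 each, log2 fold change -1.84, SE 0.13, limma adjusted p = 0.00374). In sorted cells, Chd4dPax7ER replicates held 64.1, 50.4, 63.8 and 48.7 RPKM and Chd4fl/fl replicates 135.1, 125.8, 118.6 and 126.0. This left 44.9% of control (56.7 ± 8.37 against 126.4 ± 6.77, log2 fold change -1.16, SE 0.10, adjusted p = 0.000152). Over all arrangements of the libraries the exact permutation p was 0.0286 in each setting, the smallest that 70 can give. In vitro this ignores the pairing by replicate number, and within the pairs it was 0.125, the smallest that 16 can give. The transcript was reduced, not absent, in all 8 case libraries. How much of the rest came from cells that kept the gene, or from a transcript lacking the deleted part, was not measured.

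**Figure D1:**
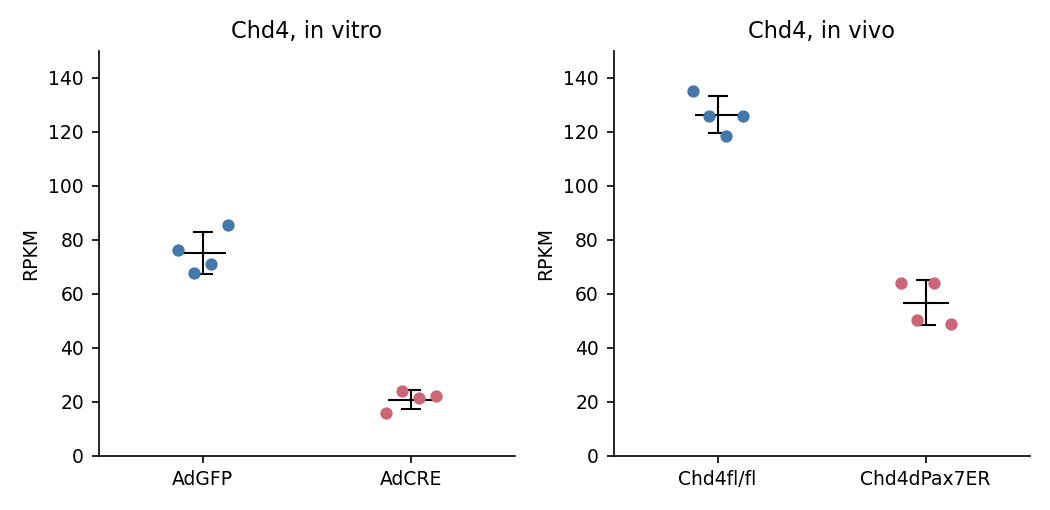
Chd4 in every library, in RPKM (y axis), by group (x axis). Points are libraries and bars show mean ± SD; case means were 27.7% of control in vitro and 44.9% in vivo.

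Among genes that passed and whose groups did not overlap, Sncg rose most in proliferating myoblasts after AdCRE. This gene, which encodes gamma-synuclein of neurons, went from 0.744 ± 0.296 RPKM in AdGFP to 9.23 ± 4.48 in AdCRE (n = 4 each, log2 fold change 2.88, SE 0.36, adjusted p = 0.0175). Ly6a, which encodes the stem and stromal cell surface protein SCA1, rose from 2.54 ± 1.06 to 12.4 ± 2.40 (2.13, SE 0.24, adjusted p = 0.0113). Rgs5, a regulator of G-protein signalling used as a pericyte marker, rose from 65.6 ± 26.2 to 273 ± 95.8 (2.06, SE 0.31, adjusted p = 0.0309). The imprinted, retrotransposon-derived Peg10 rose from 27.2 ± 4.38 to 101 ± 24.9 (1.85, SE 0.19, adjusted p = 0.00958). Efna3, an ephrin ligand, rose from 1.17 ± 0.206 to 5.71 ± 1.30 (1.87, SE 0.17), and the interferon-induced Ifit1 from 0.179 ± 0.0534 to 2.01 ± 0.617 (1.85, SE 0.19). Tubb4a (1.67, SE 0.11, adjusted p = 0.00243), a tubulin of the nervous system, and the GTPase regulator Arhgap45 (1.64, SE 0.13, adjusted p = 0.00474) rose from levels near 0.1 RPKM (0.0785 ± 0.00695 and 0.106 ± 0.0533). Gpsm3 (1.92, SE 0.23) and the collagen gene Col1a1 (1.62, SE 0.21) complete the 10 largest rises.

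Gzmd and Gzme, neighbouring granzyme genes of similar sequence, fell furthest beside Chd4. Gzmd went from 12.8 ± 3.73 to 2.51 ± 0.832 RPKM (log2 fold change -2.15, SE 0.24, adjusted p = 0.0107) and Gzme from 44.6 ± 7.86 to 18.3 ± 4.34 (-1.27, SE 0.18, adjusted p = 0.0252). Falls of Il18rap, an interleukin receptor subunit (-0.82, SE 0.13), Chchd6 (-0.76, SE 0.12), the biliverdin reductase gene Blvra (-0.75, SE 0.11), Arsb (-0.66, SE 0.11) and Tmem171 (-0.65, SE 0.09) were smaller. For each of these genes all 4 AdCRE libraries lay on one side of all 4 AdGFP libraries. The paralogous ATPase gene Chd3 held 28.6 ± 3.70 RPKM against 16.5 ± 2.87 (0.78, SE 0.14, adjusted p = 0.0558, and 0.00016 with the replicate block). The NuRD subunit gene Mta3 held 7.24 against 5.48 RPKM (0.37, adjusted p = 0.0652, block 0.00196).

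Across the table, 70 genes rose and 19 fell, 41 and 3 of them by at least 2-fold, and 2111 genes had an unadjusted p under 0.05. With the replicate number as a block, which removes the differences that same-numbered cultures share, 2371 rose and 2536 fell, among them all 89 genes called without it. Leaving out the pair of replicate 4 gave 1555 and 1602 with the block. The groups of 1358 genes (10.0%) did not overlap. Without the block the counts rest on every library. Leaving out AdCRE replicates 1, 2, 3 and 4 in turn, 40, 14, 27 and 28 genes rose and 4, 2, 3 and 3 fell. Leaving out AdGFP replicates 1, 2, 3 and 4 in turn, 23, 20, 18 and 22 rose and 3, 3, 2 and 3 fell. Chd4, Efna3, Ifit1, Peg10, Tubb4a and Arhgap45 passed in all 8 of these fits. Gzmd missed the threshold without AdCRE replicate 2 (adjusted p = 0.0536) and Ly6a without AdCRE replicate 2 or AdGFP replicate 3 (up to 0.0557). Sncg missed it without AdCRE replicate 2 or any AdGFP library (up to 0.0770) and Gpsm3 without AdCRE replicates 2 or 3 or AdGFP replicates 1, 2 or 4 (up to 0.0708). Rgs5 and Tmem171 passed only without AdGFP replicate 4, Col1a1 only without AdCRE replicate 1 and Gzme only without AdCRE replicate 3 (otherwise up to 0.124, 0.108, 0.0782 and 0.0939). Il18rap, Chchd6, Blvra and Arsb missed it whichever library was left out (up to 0.161). These losses belong to the fit that ignores the pairing. With the block and all libraries, limma's adjusted p was 5.03e-05 for Rgs5 and 0.00016 for both Sncg and Gzme. It was 0.000506 for Il18rap, 0.00106 for Chchd6, 0.000349 for Blvra and 0.000805 for Arsb.

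**Figure D2:**
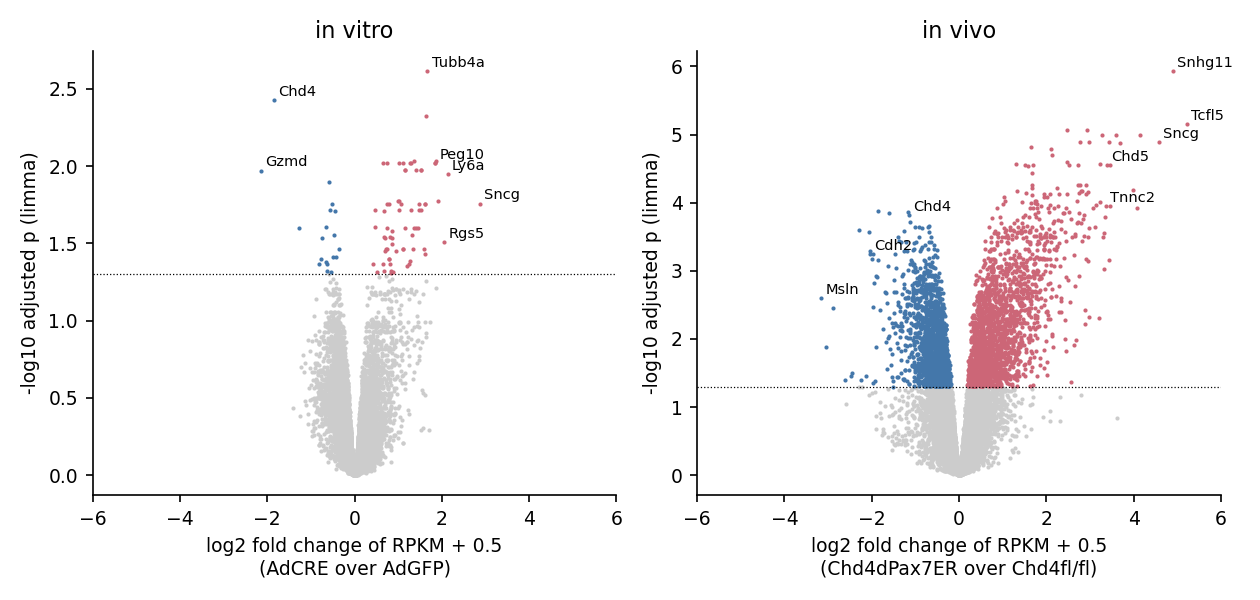
Log2 fold change of RPKM + 0.5 (x axis) against -log10 of limma's adjusted p (y axis) for every gene tested, in vitro and in vivo. Red genes were higher and blue genes lower in the case group, grey genes did not pass, and the dotted line marks 0.05. In all, 70 genes rose and 19 fell in vitro, and 1960 rose and 1588 fell in vivo.

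Of the gene lists in the cultures, interferon response genes rose in part, with 3 of 8 tested members passing (6 adjusted over the list alone, 19 in the list). Ifit1 was above the filter in AdCRE libraries alone. Beside Ifit1 these were Isg15 (3.92 ± 0.939 against 0.980 ± 0.506 RPKM, log2 fold change 1.61, SE 0.25, adjusted p = 0.0371) and Rsad2 (1.76 ± 0.493 against 0.497 ± 0.103, 1.17, SE 0.16, adjusted p = 0.0252). This list passed with camera (adjusted p = 3.12e-07) and, alone among the lists, with an estimated correlation (adjusted p = 0.0388), though not with the block and an estimated correlation together (0.236). Isg15 passed only without AdGFP replicate 2 and Rsad2 only without AdCRE replicate 1 (otherwise up to 0.142 and 0.108), while the list passed camera without each library. Cell cycle genes had a median of -0.71. None of 24 passed over all genes, 7 fell when adjusted over the list alone, and with the block 23 fell and 1 rose. Among them Mcm4 of the replicative helicase held 38.7 ± 6.02 against 58.5 ± 9.13 RPKM (-0.59, SE 0.14, adjusted p = 0.112, block 0.000232). Pcna, the replication clamp, held 36.2 ± 7.54 against 58.4 ± 9.84 (-0.69, SE 0.18, adjusted p = 0.134, block 0.000349). Camera gave the cell cycle list an adjusted p of 1.06e-08, or 0.430 with an estimated correlation.

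Of 22 p53 targets none passed over all genes and 5 rose over the list alone (11 with the block), with a median of 0.16 (camera adjusted p = 0.000388, 0.138 with an estimated correlation). The stress-induced cytokine gene Gdf15 held 19.4 ± 6.81 against 6.98 ± 2.57 RPKM (1.44, SE 0.33, adjusted p = 0.108, block 0.000671). Perp held 2.09 ± 0.413 against 0.977 ± 0.183 (0.80, SE 0.15, adjusted p = 0.0653, block 0.000631). Of 7 neuronal genes none passed, 2 rose over the list alone and 4 with the block (median 0.80, camera adjusted p = 0.00813, 0.138 with an estimated correlation). The ubiquitin hydrolase gene Uchl1 held 11.7 ± 4.52 against 3.73 ± 2.23 RPKM (1.63, SE 0.40, adjusted p = 0.120, block 0.000438). Myogenic differentiation genes had a median of 0.33. None of 21 passed, over the list alone either, and 19 rose with the block. The slow troponin gene Tnnt1 held 184 ± 67.1 against 120 ± 58.0 RPKM (0.69, SE 0.44, adjusted p = 0.507, block 0.00140). That list had a camera adjusted p of 0.0202, or 0.769 with an estimated correlation. It missed the threshold without AdCRE replicates 2 or 3 or AdGFP replicates 1 or 4 (up to 0.729).

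Camera also called 8 shorter or weaker lists higher in AdCRE. Notch and quiescence genes (14, median 0.29, 1 higher and 1 lower over the list alone, 9 and 1 with the block) had an adjusted p of 0.0202. Adipogenic genes (9, median 0.46, 8 higher and 1 lower with the block) also had 0.0202. Imprinted genes (15, median 0.26) had 0.0114, with Peg10 passing, 3 higher over the list alone and 8 higher and 1 lower with the block. Immediate early and heat shock genes (20, median 0.20, 1 higher over the list alone, 11 with the block) had 0.0294. Epithelial genes (5, median 0.84, Krt19 passing, 4 with the block) had an adjusted p of 0.0275. Krt19 itself (1.34 ± 0.242 against 0.539 ± 0.107 RPKM, 0.82, SE 0.14, adjusted p = 0.0478) missed the threshold whichever library was left out (up to 0.166). Fibroblast markers (3, with Ly6a passing and 3 with the block) had 0.0114, and pericyte markers (3, with Rgs5 passing and 2 with the block) 0.0275. Endothelial markers (3, 2 higher over the list alone) had 0.0294, which became 0.0687 with the block. With an estimated correlation these lists had adjusted p-values of 0.221 (adipogenic, imprinted, endothelial, fibroblast and pericyte), 0.258 (Notch), 0.521 (epithelial) and 0.699 (immediate early). Calls were lost without AdCRE replicate 4 or AdGFP replicate 1 (Notch, up to 0.0699), AdGFP replicate 4 (adipogenic, 0.0634) and AdGFP replicate 1 (imprinted, 0.0557, and pericyte, 0.101). The epithelial call was lost without AdCRE replicates 1 or 4 or AdGFP replicates 2 or 3 (up to 0.112), and the immediate early call without AdCRE replicates 1, 2 or 3 or AdGFP replicates 1 or 4 (up to 0.362). The endothelial call was lost without AdCRE replicates 2 or 4 or AdGFP replicate 1 (up to 0.119).

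The other lists in the cultures did not pass. Of 14 NuRD genes only Chd4 passed (camera adjusted p = 0.470), with 2 higher over the list alone and 4 higher and 2 lower with the block. No member passed limma, over all genes or over the list alone, among satellite cell identity (17 tested, 0.839), cardiac (8, 0.196), smooth muscle (5, 0.537) or chondrogenic and osteogenic genes (7, 0.342). The same held for senescence-associated secretion (7, 0.860), TGF-beta and BMP (13, 0.435), glycolysis (16, 0.968), Schwann (3, 0.968) and mature myofibre genes (11, 0.167). Col1a1 was the 1 extracellular matrix gene of 17 that passed (0.582). With an estimated correlation their adjusted p-values lay between 0.522 and 0.977. With the block, satellite identity had 1 higher and 3 lower, smooth muscle 2 higher, chondrogenic 3 and 1 and senescence 4 and 2. TGF-beta had 2 higher, glycolysis 4 and 2, extracellular matrix 5 and 7 and Schwann 1 higher. The block also made camera call cardiac genes (6 of 8 higher, adjusted p = 0.00805, 0.378 with an estimated correlation) and mature myofibre genes (8 of 11 higher, 0.000521, 0.315 with an estimated correlation). Median, mean and camera's direction differed in sign for NuRD (0.01, -0.05, up), satellite identity (0.02, -0.02, up), extracellular matrix (-0.13, 0.09, up), glycolysis (-0.05, 0.05, up) and Schwann genes (0.02, 0.02, down). Germline (1 member tested), macrophage (2), tenocyte (2), neutrophil (0) and erythroid genes (0) were too few for camera and none passed limma. Of the macrophage genes Laptm5 held 16.0 ± 5.83 against 5.09 ± 2.75 RPKM (adjusted p = 0.102, block 0.000134).

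In regenerating muscle, the genes that rose most in Chd4dPax7ER cells started from different levels in Chd4fl/fl satellite cells. Tcfl5, a transcription factor gene known from the testis, rose from 0.175 ± 0.169 to 24.4 ± 5.26 RPKM (n = 4 each, log2 fold change 5.21, SE 0.22, adjusted p = 6.95e-06). Sncg rose from 2.08 ± 0.839 to 58.9 ± 8.72 (4.58, SE 0.25, adjusted p = 1.29e-05) and Lum, the proteoglycan lumican, from 1.96 ± 0.318 to 43.9 ± 13.2 (4.14, SE 0.21, adjusted p = 1.02e-05). Casq1, the calcium-binding protein of the sarcoplasmic reticulum, rose from 10.7 ± 2.41 to 130 ± 64.8 (3.45, SE 0.29, adjusted p = 0.000112). Icam1, a leukocyte adhesion molecule, rose from 2.47 ± 1.46 to 43.3 ± 7.79 (3.98, SE 0.29, adjusted p = 6.44e-05). The noncoding Snhg11 (4.89, SE 0.16), Akr1c13 of a family of near-identical genes (4.08, SE 0.34), the neuronal kinase-like gene Camkv (3.68, SE 0.20), the X-linked homeobox gene Esx1 (3.59, SE 0.18) and the sperm channel gene Catsperz (3.44, SE 0.42) complete the 10 largest rises.

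Among genes that passed and whose groups did not overlap, Msln (mesothelin) fell furthest in vivo, from 29.0 ± 1.74 to 4.13 ± 4.90 RPKM (-3.15, SE 0.51, adjusted p = 0.00252) and Dynap fell from 27.7 ± 9.22 to 4.21 ± 4.31 (-2.88, SE 0.50, adjusted p = 0.00353). Cdh2, the N-cadherin of the satellite cell niche, fell from 34.1 ± 1.80 to 8.45 ± 3.46 (-2.03, SE 0.24, adjusted p = 0.000571). Cd109 (-2.05, SE 0.21), the receptor phosphatase gene Ptprk (-1.99, SE 0.24), the prostacyclin synthase gene Ptgis (-2.29, SE 0.23) and Tigit (-1.98, SE 0.34) fell as well. The small nucleolar RNA genes Snord87 (-3.06, SE 0.71) and Snord4a (-2.47, SE 0.74) fell too. Snord4a missed the threshold without Chd4dPax7ER replicate 2 or Chd4fl/fl replicates 2, 3 or 4 (up to 0.0903), and also with a pseudocount of 0.1, no filter, TPM scaling or no trend (up to 0.0741). For each of these genes, rising or falling, all 4 libraries of one group lay on one side of the other 4. In all, 1960 genes rose and 1588 fell, 748 and 184 of them by at least 2-fold. Together these were 26.6% of the genes tested, the share to set beside counts of list members. Higher genes made up 55.2% of calls, but 46.4% with TPM scaling and 47.3% with quantile scaling, so among calls of any size the direction that prevailed changed with the scaling. The groups of 4049 genes (30.3%) did not overlap, against 2.86% by chance, and without Chd4fl/fl replicate 2 the genes that fell numbered 1034.

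Among NuRD genes in vivo, the Chd4 paralogue Chd5 rose from 0.177 ± 0.112 to 6.67 ± 1.64 RPKM (3.39, SE 0.21, adjusted p = 2.8e-05) and Chd3 from 31.8 ± 2.78 to 61.8 ± 4.58 (0.95, SE 0.08, adjusted p = 0.00016). Mta1 fell (-0.57, SE 0.10, adjusted p = 0.00425). Of 15 genes 4 rose, 4 fell and 7 did not pass, also over the list alone, so the list had no direction (camera adjusted p = 0.946, 0.969 with an estimated correlation). Mta3 (0.66), Hdac1 (0.34), Rbbp4 (-0.29) and Gatad2b (-0.26) passed with all libraries but missed the threshold without 2, 4, 4 and 7 of the 8 in turn (up to 0.0623, 0.0633, 0.0720 and 0.0786). These were Chd4dPax7ER replicates 2 and 4 for Mta3, and Chd4dPax7ER replicates 3 and 4 and Chd4fl/fl replicates 2 and 4 for Hdac1. Rbbp4 missed it without Chd4dPax7ER replicates 2 or 3 or Chd4fl/fl replicates 1 or 2 and Gatad2b without any but Chd4dPax7ER replicate 3.

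Many skeletal muscle genes rose in Chd4dPax7ER cells, though no muscle list passed with an estimated correlation. Tnnc2, the fast troponin C gene, rose from 44.4 ± 15.8 to 446 ± 114 RPKM (3.36, SE 0.28, adjusted p = 0.000113). The perinatal myosin gene Myh8 rose from 1.12 ± 0.491 to 13.8 ± 10.5 (2.89, SE 0.51, adjusted p = 0.00380) and Acta1, skeletal actin, from 132 ± 44.4 to 477 ± 252 (1.79, SE 0.34, adjusted p = 0.00559). Chd4dPax7ER replicate 2 held the most of all 3 (610, 27.2 and 852 RPKM), and without it they rose by 3.20, 2.46 and 1.47 and passed. Of 22 differentiation genes 16 rose, none fell and 6 did not pass, and also over the list alone (median 1.21, camera adjusted p = 1.37e-07, 0.436 with an estimated correlation). Of 11 mature myofibre genes, 6 of which the differentiation list also holds, 10 rose and 11 over the list alone (median 1.35, camera adjusted p = 1.76e-05, 0.436 with an estimated correlation). Cardiac genes had 3 of 5 tested members higher (24 in the list), also over the list alone (camera adjusted p = 0.0292, 0.436 with an estimated correlation). Among them was the slow troponin C gene Tnnc1 (65.2 ± 37.2 against 17.7 ± 5.54 RPKM, 1.78, SE 0.36), and the list missed the threshold without Chd4dPax7ER replicate 2 (0.0503), without the filter (0.0506) and with the stricter filter (0.0879). Smooth muscle genes had 2 of 8 higher and 1 lower, or 4 and 1 over the list alone (camera adjusted p = 0.200, 0.633 with an estimated correlation). Tagln was higher (1.27, SE 0.31) and Cald1 lower (-0.61, SE 0.10).

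Satellite cell genes moved both ways. Myod1, the myogenic determination factor, rose from 65.7 ± 10.5 to 132 ± 21 RPKM (1.00, SE 0.14, adjusted p = 0.00110). The surface proteoglycan gene Sdc3 rose from 7.52 ± 0.432 to 19.8 ± 2.12 (1.33, SE 0.10, adjusted p = 6.71e-05) while the growth factor receptor gene Fgfr4 fell from 52.3 ± 5.56 to 25 ± 5.13 (-1.07, SE 0.13, adjusted p = 0.000812). Of 18 identity genes 7 rose, 3 fell and 8 did not pass, or 8 and 4 over the list alone (camera adjusted p = 0.111, 0.466 with an estimated correlation). Pax7, chosen after its values were seen, fell from 21.3 ± 6.43 to 11.5 ± 2.94 (-0.85, SE 0.24, adjusted p = 0.0301). Its groups overlap, and it did not pass without Chd4dPax7ER replicates 2 or 4 or Chd4fl/fl replicates 3 or 4 (up to 0.0733). The case genotype label names Pax7ER, and any effect of that part of the genotype on Pax7 was not told apart from Chd4 loss. Of 17 Notch and quiescence genes 1 rose (Foxo1, 0.82, SE 0.13) and 3 fell, also over the list alone, near the share of all genes called (26.6%). Of those that fell, Spry1 (-0.92) missed the threshold in 6 of the fits without 1 library and Cdkn1b (-0.36) in 4 (adjusted p up to 0.0767 and 0.0727). Hey1, a Notch target, fell from 23.5 ± 2.70 to 16.6 ± 2.52 (-0.49, SE 0.12, adjusted p = 0.0159). The Notch list did not pass (camera adjusted p = 0.792, 0.907 with an estimated correlation), with a median of 0.14 and a mean of -0.04.

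Of the p53 targets, the cell cycle inhibitor gene Cdkn1a rose (281 ± 12.9 to 669 ± 134 RPKM, 1.23, SE 0.12, adjusted p = 0.000255). Ccng1 (46.3 ± 4.39 to 127 ± 20.8, 1.43, SE 0.11, adjusted p = 9.74e-05) and Trp53inp1 (13.3 ± 1.19 to 44.2 ± 6.10, 1.69, SE 0.11) rose as well. Of 21 targets 12 rose and 1 fell, or 13 and 1 over the list alone (median 0.58, camera adjusted p = 1.76e-05, 0.196 with an estimated correlation). Cell cycle genes had 6 of 24 lower and 1 higher, also over the list alone (median -0.44, camera adjusted p = 0.000891, 0.566 with an estimated correlation). Bub1 of the spindle checkpoint fell from 21.1 ± 2.81 to 11 ± 2.93 (-0.94, SE 0.18, adjusted p = 0.00565). The G1 cyclin gene Ccnd1 rose from 23.1 ± 5.63 to 52.1 ± 7.34 (1.2, SE 0.17, adjusted p = 0.00155). None of 14 senescence-associated secretion genes passed limma (camera adjusted p = 0.792, 0.907 with an estimated correlation). Glycolysis genes had 10 of 16 higher and 1 lower, or 10 and 2 over the list alone (median 0.32, camera adjusted p = 0.000864, 0.172 with an estimated correlation). Pfkp rose from 24.8 ± 1.79 to 43.5 ± 3.38 RPKM (0.80, SE 0.08), and the hexokinase gene Hk1 rose by 0.81 (SE 0.10).

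Signalling and other lineage genes rose in part. TGF-beta and BMP targets had 3 of 11 higher, or 5 over the list alone (median 0.49, camera adjusted p = 0.0106, 0.436 with an estimated correlation). They were led by the matrix gene Ltbp2 (0.820 ± 0.116 to 12.4 ± 2.39 RPKM, 3.27, SE 0.16, adjusted p = 1.02e-05). Interferon response genes had 6 of 18 higher, also over the list alone (camera adjusted p = 0.0137, 0.494 with an estimated correlation). Bst2, a restriction factor, rose from 18.2 ± 5.39 to 48.2 ± 5.52 (1.42, SE 0.20). The list missed the threshold without Chd4dPax7ER replicates 2 or 3 or Chd4fl/fl replicate 1 (up to 0.0793). Neuronal genes had 4 of 6 tested members higher (22 in the list), or 5 higher and 1 lower over the list alone (camera adjusted p = 0.0132, 0.436 with an estimated correlation). Uchl1 rose from 2.74 ± 1.2 to 25.6 ± 4.87 (3.07, SE 0.26). Of the neuronal genes that rose, Nefm (mean 1.58 against 0.193 RPKM) and Elavl3 (0.745 against 0.140) were above the filter in Chd4dPax7ER libraries alone. Elavl3 missed the threshold without Chd4fl/fl replicate 2 (limma adjusted p = 0.0510). Imprinted genes went both ways, 7 of 16 higher and 3 lower (8 and 5 over the list alone, camera adjusted p = 0.144, 0.466 with an estimated correlation). The growth factor gene Igf2 rose from 25.8 ± 7.27 to 112 ± 44.6 (2.08, SE 0.28, adjusted p = 0.00105) and Mest fell from 309 ± 72.5 to 84.0 ± 33.4 (-1.91, SE 0.26, adjusted p = 0.00118). Adipogenic genes had 5 of 9 higher, also over the list alone (adjusted p = 0.133, 0.440 with an estimated correlation), led by Ppargc1a (1.75, SE 0.26). Immediate early and heat shock genes had 5 of 21 higher, or 7 over the list alone (0.0519, 0.599 with an estimated correlation), led by the small heat shock gene Hspb1 (1.54, SE 0.16). Chondrogenic and osteogenic genes had 3 of 6 higher and 1 lower (adjusted p = 0.192, 0.436 with an estimated correlation), with Runx2 lower (-0.72, SE 0.13). Extracellular matrix genes had 5 of 19 higher and 1 lower (adjusted p = 0.137, 0.703 with an estimated correlation), with Bgn higher (1.30, SE 0.19). The counts of these last 2 lists were the same over each list alone.

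Markers of other cell types were measured beside these groups. Of 11 fibroblast and FAP markers 5 rose, or 6 over the list alone (median 0.77, camera adjusted p = 0.000625, 0.436 with an estimated correlation). They include Lum and the proteoglycan gene Dcn (10.9 ± 1.81 to 109 ± 32.7 RPKM, 3.23, SE 0.20, adjusted p = 2.67e-05). Of 7 pericyte markers 5 rose, or 6 over the list alone (median 1.42, adjusted p = 0.00275, 0.436 with an estimated correlation), with Abcc9 (1.64, SE 0.27) and Cspg4 (1.43, SE 0.28). Of 8 Schwann and glial markers 4 rose, or 5 over the list alone (median 1.26, adjusted p = 0.00148, 0.436 with an estimated correlation). The glial transcription factor gene Sox10 rose from 0.175 ± 0.132 to 3.13 ± 0.926 (2.42, SE 0.24) and the myelin gene Mbp from 0.662 ± 0.495 to 7.14 ± 0.995 (2.79, SE 0.26). Macrophage and leukocyte markers had 1 of 12 higher (Laptm5, 1.01, SE 0.20), with a list adjusted p of 0.105, or 0.599 with an estimated correlation. Endothelial markers had 1 of 3 higher (Cldn5, 1.96, SE 0.32), with 0.144, or 0.436 with an estimated correlation. Tenocyte markers had 1 of 4 higher (Tnxb, 1.78, SE 0.39), with 0.144, or 0.466 with an estimated correlation. These 3 counts were the same over each list alone. Too few for camera were the epithelial keratin genes Krt18 (-1.74, SE 0.35) and Krt8 (-1.34, SE 0.32), which fell, and the germline gene Piwil2, which rose (1.06, SE 0.27) but not without Chd4dPax7ER replicate 4 (adjusted p = 0.0526). The erythroid gene Hba-a1 was listed at 0 in all 4 Chd4fl/fl libraries and at 0.55, 4.03, 0.76 and 0.73 RPKM in Chd4dPax7ER replicates 1 to 4. No neutrophil marker was expressed enough to test. Ly6a, whose product SCA1 was gated out, held 8.86 ± 2.93 against 5.52 ± 3.05 RPKM and did not pass (adjusted p = 0.191).

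**Figure D3:**
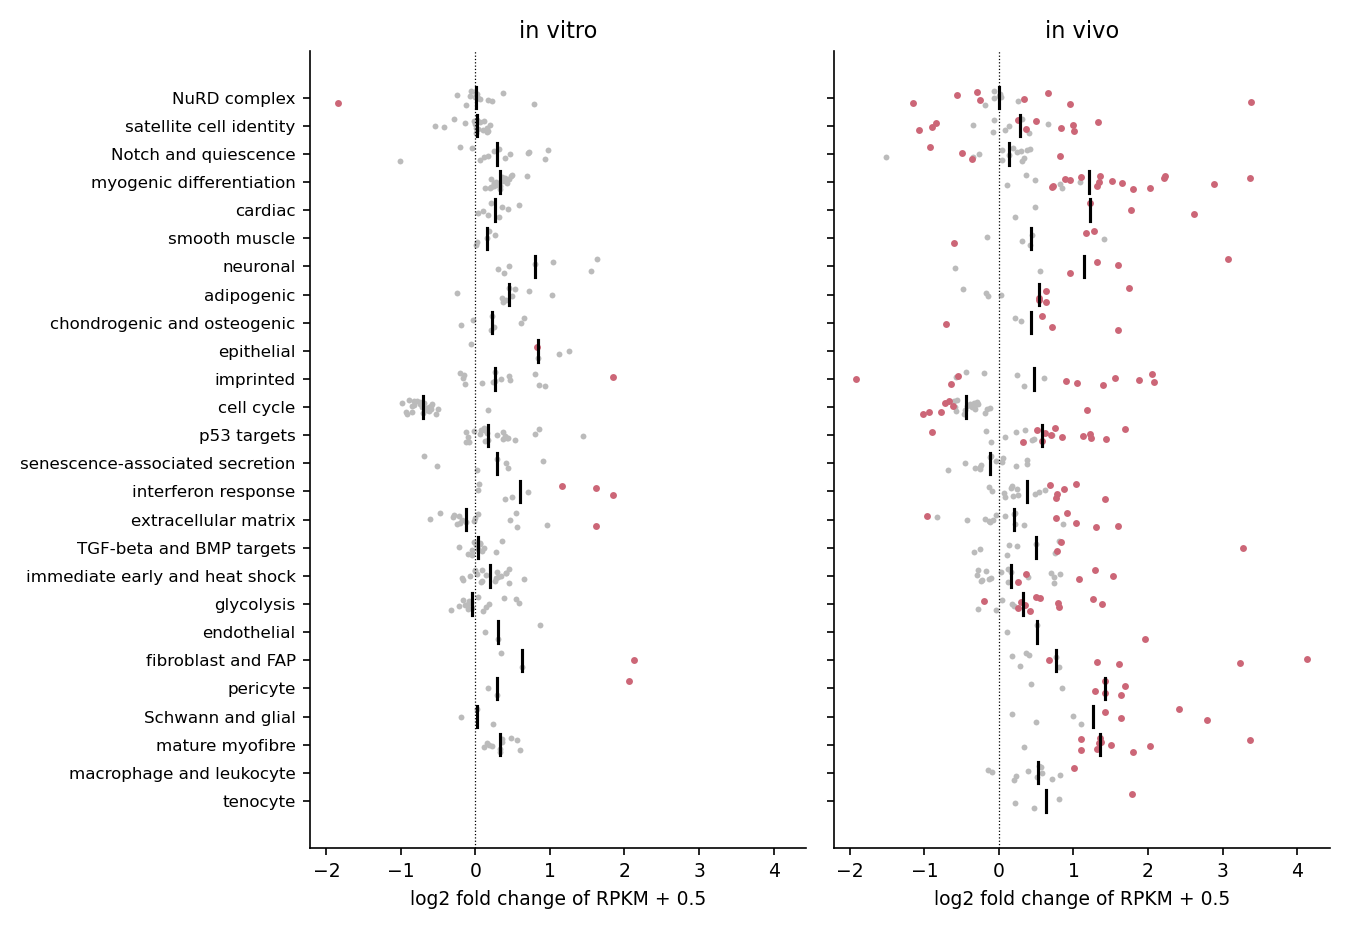
Log2 fold changes of the members of gene lists (x axis) by list (y axis), in vitro and in vivo. Points are genes, red where they passed and grey where not, and black bars are medians. The differentiation list has a median of 0.33 in vitro and 1.21 in vivo.

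Of all genes tested in vivo 26.6% passed. The shares of members that passed in the Notch, cell cycle, TGF-beta, immediate early and extracellular matrix lists lay near this, so those counts alone say little about the lists. The list calls in vivo rest on camera's preset correlation. With it 12 of 25 lists passed, none with an estimated correlation (2 at an unadjusted p under 0.05, lowest adjusted p = 0.172) and 15 with fry. As many lists came out in 11 of the 35 divisions of these 8 libraries, the real one included, so chance is not excluded for the number of lists, while no division but the real one gave over 3 genes.

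Changes found in the cultures without the block were mostly found in sorted cells too, and a smaller share of those found with it. Of 11941 genes tested in both, 61 rose and 17 fell in vitro without the block; 47 rose in both (8.78 expected of independent lists, Fisher p = 4.38e-28 across genes) and 13 fell in both (2.2 expected, Fisher p = 3.54e-09 across genes). Sncg rose by 2.88 and 4.58 in vitro and in vivo, Gpsm3 by 1.92 and 3.34, Tubb4a by 1.67 and 2.07 and Arhgap45 by 1.64 and 2.27. Rgs5 rose by 2.06 and 1.69, but in vivo not without Chd4dPax7ER replicates 2 or 3 or Chd4fl/fl replicates 1, 2 or 4 (adjusted p up to 0.114). Il18rap (-0.82 and -1.46), Chchd6 (-0.76 and -0.75), Blvra (-0.75 and -0.74) and Arsb (-0.66 and -0.72) fell in both beside Chd4. In vivo Chchd6 missed the threshold without Chd4dPax7ER replicates 2 or 4 or Chd4fl/fl replicates 1 or 3 (adjusted p up to 0.0748). Of the in vitro calls shared here, those of Tubb4a, Arhgap45 and Chd4 passed without each library in turn. Only 2 genes passed in opposite directions, Glt8d2 (0.75 and -0.87) and Lrrn1 (0.65 and -0.69), named after their values were seen. In vitro these 2 missed the threshold whichever library was left out (adjusted p up to 0.128 and 0.144). Fold changes of all these genes correlated (Pearson r = 0.559, Spearman correlation 0.536). With the block for the cultures, 952 of the 2106 genes higher in vitro rose in both and 718 of the 2411 lower fell in both (303.0 and 309.5 expected), while 55 and 47 went opposite ways (270.4 and 346.9 expected). Without the block, the 60 shared calls became 31, 10, 21 and 21 without AdCRE replicates 1 to 4 in turn and 18, 15, 14 and 17 without AdGFP replicates 1 to 4.

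The size of the effect differed for 524 genes (2293 at an unadjusted p under 0.05), and in 502 of them the change was larger in vivo; 307 had the same sign in both. Ass1, an enzyme of arginine synthesis, changed by -0.07 in vitro and 2.47 in vivo (difference -2.54, SE 0.17, adjusted p = 6.22e-07). The actin-binding gene Twf2 changed by 0.06 and 2.48 (-2.42, SE 0.19) and Gas6, a growth factor for TAM receptors, by -0.08 and 2.97 (-3.05, SE 0.27). Tcfl5 rose by 1.60 and 5.21 (-3.61, SE 0.30) and Isyna1 by 0.15, not passing, and 1.29 (-1.15, SE 0.11). On the other side were Peg10 (1.85 and -0.57, the latter not passing; difference 2.42, SE 0.27, adjusted p = 9.73e-05) and the secreted protease gene Htra3 (1.01, not passing without the block, and -1.15; 2.16, SE 0.28). So were Far1 (-0.04 and -0.84; 0.80, SE 0.10), the cell cycle kinase gene Cdk6 (0.13 and -1.0; 1.13, SE 0.16) and Copg2 (0.33 and -0.54; 0.87, SE 0.13). Chd4 itself fell further in the cultures (difference -0.68, SE 0.17, adjusted p = 0.0334), and Sncg (-1.70, SE 0.44) and Gpsm3 (-1.42, SE 0.38) rose further in vivo. These 3 differences were weak: Chd4 missed the threshold without AdCRE replicate 3, AdGFP replicates 1, 3 or 4, Chd4dPax7ER replicates 1 or 3 or Chd4fl/fl replicates 2, 3 or 4 (adjusted p up to 0.0657). Sncg missed it without AdCRE replicates 2 or 4, AdGFP replicates 1, 2 or 3, Chd4dPax7ER replicates 1, 2 or 4 or Chd4fl/fl replicates 1 or 2 (up to 0.0985). Gpsm3 missed it without AdCRE replicates 2, 3 or 4, AdGFP replicates 2 or 3, Chd4dPax7ER replicates 2, 3 or 4 or Chd4fl/fl replicates 1, 2 or 4 (up to 0.0988). Sncg and Gpsm3 were low in AdGFP (means 0.744 and 0.478 RPKM), where adding 0.5 shrinks fold changes. How much of their differences came from this was not tested. The other differences named passed without each of the 16 libraries, while the in vitro call of Tcfl5 was lost without AdCRE replicate 2 or any AdGFP library (up to 0.0773). Culture against tissue, proliferation against injury and virus against genotype all part the 2 settings, so a difference between them has no single reading. With the block for the cultures 1749 genes differed. In the fit without it, leaving out AdCRE replicate 2, AdCRE replicate 3 or AdGFP replicate 3 gave 319, 326 and 301 effects that differ. The count was 347, 324, 324 and 339 without Chd4dPax7ER replicates 2 and 4 and Chd4fl/fl replicates 2 and 3.

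**Figure D4:**
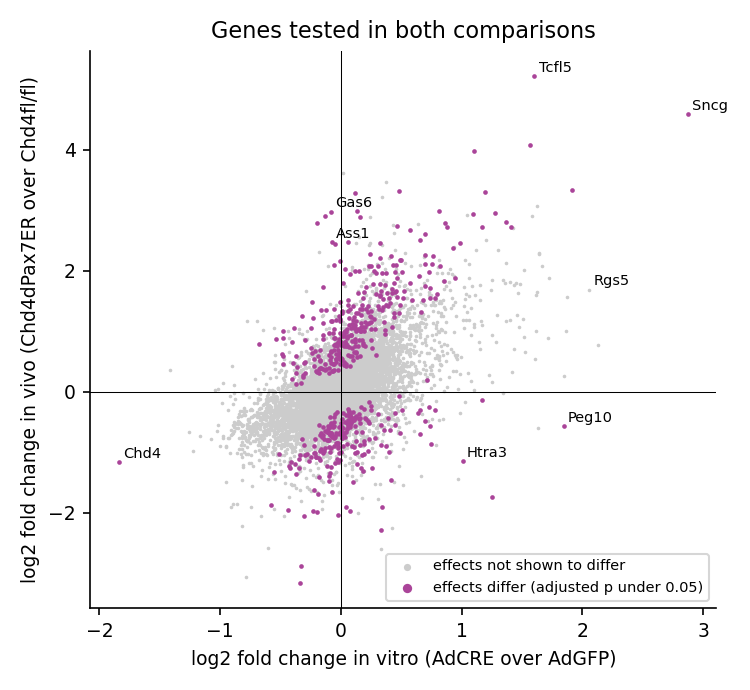
Log2 fold changes in vitro (x axis) and in vivo (y axis) for the 11941 genes tested in both settings. Each point is a gene, and purple points are the 524 genes whose effects differ, with a Pearson r of 0.559.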

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

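The tests of explanations below and the other divisions of the libraries were chosen after the results were seen; the search for stray libraries and the test of differences between settings were planned. Dixon's ratio of gap to range was computed for each group of 4 behind a reported gene or library measure, 292 groups in all, of which 26 passed the critical value for 4 values. Chance alone would pass about 1 in 20 groups.

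Chd4dPax7ER replicate 2 stood above the other 3 libraries of its group for 8 genes: Casq1 (226.6 against 92.6 to 106.4 RPKM, ratio 0.897), Tnnc1 (120.7 against 41.1 to 49.6, 0.893), Acta1 (852 against 323 to 399, 0.857), Igf2 (179 against 87.6 to 95.1, 0.918), Cdkn1a (868 against 586 to 626, 0.857), Hspb1 (69.2 against 55.5 to 57.2, 0.879), Hk1 (36.7 against 30.4 to 31.2, 0.869) and Hba-a1 (4.03 against 0.55 to 0.76, 0.940). It also had the highest mean log2 level of fibroblast, pericyte and Schwann markers (3.20) and of macrophage markers (3.00), so these markers and the muscle genes were high together in it. Chd4dPax7ER replicate 1 kept more of several genes that fell: Msln (11.5 against 1.26 to 2.04 RPKM, 0.924), Dynap (10.6 against 1.64 to 2.91, 0.859), Fgfr4 (32.6 against 21.9 to 22.9, 0.904), Il18rap (2.04 against 0.68 to 0.76, 0.941) and Blvra (4.35 against 2.97 to 3.16, 0.862). Chd4dPax7ER replicate 3 was low for Akr1c13 (9.16 against 13.5 to 14.3, 0.841). Among the Chd4fl/fl libraries, replicate 1 was low for Tnnc1 (9.40 against 20.4 to 20.7, 0.973) and Arsb (6.53 against 8.21 to 8.49, 0.857), replicate 3 for Sdc3 (6.88 against 7.67 to 7.80, 0.859), and replicate 4 was high for Laptm5 (3.76 against 2.33 to 2.42, 0.937). Casq1, Tnnc1, Acta1, Igf2, Cdkn1a, Hspb1, Hk1, Msln, Dynap, Fgfr4, Akr1c13, Sdc3 and Laptm5 passed in vivo without each library in turn.

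In the cultures, AdCRE replicate 1 was high for Rsad2 (2.50 against 1.49 to 1.54 RPKM, ratio 0.944), AdCRE replicate 4 for Ass1 (82.7 against 62.9 to 64.2, 0.937) and AdCRE replicate 3 for Far1 (20.6 against 18.6 to 18.8, 0.869). AdGFP replicate 4, the deepest library, was low for Sncg (0.303 against 0.861 to 0.921, 0.903), high for Ass1 (89.1 against 64.2 to 67.5, 0.866) and held more genes above 0 than its group (0.939). AdGFP replicate 3 was low for Glt8d2 (0.428 against 0.569 to 0.589, 0.871), and AdGFP replicate 1 had a low share of ribosomal protein transcripts (3.88% against 4.26 to 4.28%, 0.929).

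Effects that differ between cultures and sorted cells numbered 524. The log2 fold change in vitro less that in vivo was 2.42 for Peg10, 2.16 for Htra3, 0.80 for Far1, 1.13 for Cdk6 and 0.87 for Copg2, and -2.54 for Ass1, -2.42 for Twf2, -3.61 for Tcfl5, -3.05 for Gas6 and -1.15 for Isyna1. For Glt8d2 and Lrrn1, which passed with opposite signs, it was 1.62 and 1.34, and for genes that passed in both with the same sign -1.70 (Sncg), -1.42 (Gpsm3) and -0.68 (Chd4).

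Some markers of fibroblasts (5 of 11), pericytes (5 of 7) and Schwann cells (4 of 8) rose in Chd4dPax7ER cells while muscle genes rose too, though none of these 3 lists passed with an estimated correlation (adjusted p = 0.436 each). A lower share of satellite cells would raise markers of every other cell type alike, yet the mean of all 26 markers tested rose by 1.29 and that of 12 macrophage markers by 0.44 (exact permutation p = 0.143 for the latter), a difference of 0.85 with an exact permutation p of 0.0286. The sort took CD45-negative cells, but the controls still held 12 of 13 macrophage markers at 1 RPKM or more. The test was chosen after these 3 lists had passed camera and the macrophage list had not, so a difference was likely beforehand. It therefore cannot decide whether the share of satellite cells was lower, and more cells of the types that rose stays open too. Added fibroblast RNA was not excluded: Pdgfra, Mfap5, Clec3b and Smoc2, fibroblast markers with levels near 1 RPKM, changed by a mean of 0.31 (SD 0.10, exact permutation p = 0.286), while Lum and Dcn changed by 4.14 and 3.23. The control libraries already held 8 of 12 fibroblast, 4 of 9 pericyte and 4 of 9 Schwann markers at 1 RPKM or more, and the sort excluded SCA1-positive cells, which include most FAPs. Expression of these genes in the satellite cells themselves may explain the pattern but was not separated from added cells.

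Muscle genes could rise through RNA of mature fibres carried along in the sort. Adult fast fibres hold much Ckm, Pvalb and Myh4. In the 4 Chd4dPax7ER libraries these 3 genes gained only 0.676 to 1.55% of the RPKM gained by Tnnc2, Mylpf and Tnnt3. This argues against adult fast fibres as the main source of those gains, for these genes alone. The genes were chosen after their values were seen, and no fibre profile was measured. Fibre RNA in smaller amounts, or from fibres newly formed after the injury, was not excluded. The scaling of RPKM is argued against as well, since the median of the differentiation list was 1.16 or more with each of 3 other scalings. A larger share of cells that had begun to differentiate remains open and was not tested.

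Same-numbered cultures deviate together, which is why the block changes the counts. Replicates 1 and 4 express Xist and replicates 2 and 3 Y-linked genes in both virus groups. Sex type may be part of the structure: libraries of different number correlated at -0.262 to 0.438 within a sex type and at -0.291 or less across sex types. Within a sex type only replicates 2 and 3 correlated positively (0.438 and 0.390), while replicates 1 and 4 gave -0.212 and -0.262. Sex type was therefore not told apart from what else replicates 2 and 3 share. Sex alone is argued against, since a sex term called 266 genes against 4907 with the block. All same-number correlations were higher, from 0.711, which is consistent with each number being a separate cell isolate divided between the viruses, though the labels do not say so. In vivo the Y-linked libraries were Chd4dPax7ER replicate 3 and Chd4fl/fl replicate 1, with Xist at 4.61 and 1.07 RPKM.

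Other divisions of the same libraries into groups of the same size were fitted like the real one, which is counted among them. In vitro, 2 of 35 divisions called as many genes: the real one called 89 and another, replicates 1 and 4 against 2 and 3, called 717. Chance is thus not excluded from this number alone. Divisions that also keep all pairs together but cross sex type called 5 and 11 genes. The larger count thus belongs to replicates 1 and 4 against 2 and 3, which part by sex type. Sex type was not told apart from what else these replicates share. Of the 8 divisions that part all 4 pairs, as the real one does, no other called any gene without the block. With the block, too, 1 of these 8 called as many as 4907, the real one, with at most 0 in another, but 8 divisions are too few for a share under 0.05. In vivo the real division alone, 1 of 35, called as many as 3548 genes, with at most 3 in another. This is the smallest share that 35 divisions can give, so chance is unlikely for this number but not strictly excluded. For gene lists in vitro, 1 of 35 divisions called as many as 13, the real one, with at most 10 in another, but most of the others keep some pairs together, unlike the real one. Of the 8 that part all pairs, 1 called as many as the real one, with 13 lists against at most 8 without the block and 14 against at most 12 with it, and 8 divisions are too few for a share under 0.05. In vivo chance is not excluded for lists (11 of 35, 12 lists against up to 21). For both settings together, 1 of 100 pairs of divisions gave as many as 60 shared calls (at most 0 in another), but no other pair drawn called enough genes in both settings to share more than 2, so this count decides nothing. As many as 524 differing effects came from 3 of 100 pairs (up to 1956 in another), but all 3 hold the real division in vivo, and the other 2 gave more with another division in vitro. The changes in vivo alone thus give such counts, and this count decides nothing about a difference between settings.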

How the results depend on the processing

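The sex term, the block for the cultures alone, the alternatives of the blocked fit and the permutation within pairs were chosen after the results were seen; the other settings were planned. In limma Chd4 kept its sign and passed in every setting, between -1.91 and -1.72 in vitro and between -1.22 and -1.09 in vivo without 1 library. Its exact permutation p in vitro of 0.0286 became 0.125 within pairs, where 16 arrangements can give no less. Where a count moved, the cause was not tested unless stated.

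In vitro the 70 higher genes became 262 with array weights, 200 with a sex term, 12 at a threshold of 0.01 and 41 with a 2-fold minimum, and 14 to 40 without 1 library (14 without AdCRE replicate 2). The 19 lower genes became 209, 66, 1 and 3 in these settings, 12 without the filter and 2 to 4 without 1 library. Other scalings, pseudocounts, filters and limma without the trend gave 55 to 90 and 16 to 28. The 13 lists became 1 with an estimated correlation and 7 to 14 without 1 library (7 without AdGFP replicate 1).

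With the replicate block, 2371 genes rose and 2536 fell in vitro, since the block takes what same-numbered cultures share out of the error. Leaving out a pair gave 1555 to 1963 and 1602 to 2044 (1555 and 1602 without replicate 4), and dropping the filter beside the block gave 1674 lower genes. The blocked lists numbered 14 without any pair.

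In vivo, 1042 and 609 genes rose and fell at 0.01 and 748 and 184 with a 2-fold minimum. Without 1 library 1535 to 1754 rose and 1034 to 1436 fell (1034 without Chd4fl/fl replicate 2). The 12 lists became 0 with an estimated correlation in camera (2 at an unadjusted p under 0.05; fry called 15) and 10 to 15 without 1 library. The replicate block, where numbers do not pair samples, gave 1694 and 1184 genes and 12 lists.

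The 60 shared calls became 231 with array weights, 154 with a sex term, 1422 with the block in both settings, 1670 with the block for the cultures alone, and 10 to 56 without 1 library. The 524 differing effects became 1065, 874, 1367 and 1749 in these settings and 301 to 526 without 1 library.

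Of 23 called genes that the naming rule gives in vitro 6 passed without each library, and of 110 in vivo 88; of the lists 5 of 13 and 10 of 12. The other settings counted here exclude the stricter threshold, the minimum fold change, and the block together with an estimated correlation. In every setting counted 14 of the genes in vitro and 95 in vivo passed, and 1 and 0 of the lists. Each list but the in vitro interferon list was lost with an estimated correlation. The in vitro interferon list was lost with the block and an estimated correlation together (camera adjusted p = 0.236). Of the called genes named in the report, dropping the filter ended the calls of Rgs5, Il18rap, Chchd6, Arsb, Krt19, Isg15 and Rsad2 in vitro and of Snord4a, Rgs5 and Spry1 in vivo. TPM scaling ended those of Il18rap, Arsb and Krt19 in vitro and of Snord4a and Rgs5 in vivo. Krt19 was also lost with the stricter filter and quantile scaling, Rgs5 in vivo with quantile scaling, and Snord4a with a pseudocount of 0.1. Without the trend Snord4a, Rgs5, Gatad2b, Rbbp4 and Cdkn1b were lost in vivo, and with the block Gatad2b and Cdkn1b. The endothelial list in vitro was lost with quantile scaling, array weights and the block, the cardiac list in vivo without the filter and with the stricter one, and the interferon list in vivo with array weights. None of these genes and lists changed sign in any setting run.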

Other observations

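The families in this part were chosen after the data had been seen, so their p-values describe them and are not independent tests. For counts of members in vivo, 26.6% of all genes tested passed. Of 15 families 13 passed camera in vivo and 4 in vitro; with an estimated correlation 2 passed in vivo, while in vitro the lowest adjusted p was 0.132. In vivo, cytosolic ribosomal protein genes (camera adjusted p = 0.871) and integrin genes (0.255) did not pass. In Chd4dPax7ER satellite cells, 7 of 11 Bex and Tceal genes, which lie on the X chromosome and encode small proteins, were higher, none was lower and 4 did not pass. Bex2 went from 1.10 ± 0.767 to 10.4 ± 1.79 RPKM (n = 4 each, log2 fold change 2.90, SE 0.35, limma adjusted p = 0.000669). Bex4 rose by 2.30 (SE 0.41) and Bex1 from 17.6 ± 3.11 to 49.4 ± 6.01 (1.47, SE 0.13, adjusted p = 0.000164). The family's median was 1.42, and 1.29 to 1.44 under 3 other scalings (camera adjusted p = 0.00108, 0.200 with an estimated correlation). In the cultures 2 of 10 rose, and 8 with the block.

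Glutathione S-transferase genes, of the detoxification of electrophiles, had 9 of 17 higher and 1 lower in vivo. Gstt3 rose from 0.373 ± 0.112 to 8.97 ± 1.80 RPKM (3.43, SE 0.18, adjusted p = 1.29e-05), while Gsta4 fell from 13.2 ± 3.07 to 5.15 ± 1.91 (-1.33, SE 0.27, adjusted p = 0.00646). The median of 0.43 stayed between 0.40 and 0.43 under 3 other scalings, and the family passed camera also with an estimated correlation (adjusted p = 0.000388, 0.0400 with an estimated correlation); members share sequence, so single genes are less certain.

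Axon guidance genes of the semaphorin and plexin families had 12 of 25 higher and 1 lower in vivo, with Sema4d from 1.91 ± 0.142 to 5.07 ± 0.549 RPKM (1.20, SE 0.13, adjusted p = 0.000346; family median 0.47, camera adjusted p = 0.00108, 0.0526 with an estimated correlation). Troponin genes had 7 of 8 higher (median 1.56, camera adjusted p = 0.000108, 0.263 with an estimated correlation). Zinc finger genes with Zfp symbols leaned the other way, 46 of 274 lower and 12 higher, with a median of -0.16, or -0.24 to -0.16 under 3 other scalings (camera adjusted p = 0.00166, 0.0351 with an estimated correlation). A smaller share of them passed than of all genes tested in vivo (26.6%). The medians of each of these families kept their sign under TPM, median-ratio and quantile scaling. In the cultures, Mcm and Orc replication genes had 14 of 15 lower with the block and none without it (camera adjusted p = 9.82e-07 without the block, 0.474 with an estimated correlation).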
